A study of Mus musculus with 3 samples.

How the data were processed

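RNA was extracted from homogenised thymuses of diseased mice after lysis of red blood cells, and libraries were made by Illumina protocols, per the labels' protocols. Per the submitters' processing notes, Trim Galore 0.2.8.1, TopHat2 2.0.9, Cufflinks with no version given and Cuffdiff 2.1.1 were used with the mouse genome build mm10. The order and settings of these tools are not given in the sources used here. The deposited values were FPKM per gene with a lower and an upper 95% bound and a status, per the file headers, in 1 table for each of the 3 leukaemias. FPKM divides the fragments of a gene by its length and by the fragments of the library, so the authors' values hold no counts, and no count test was used.

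Each table had 25020 rows with a gene symbol and a locus. Rows whose symbol had been turned into a date (26 per table) were left out, and FPKM and its bounds were summed over the loci of each of the 286 symbols that had several, which left 24437 genes. The status was LOWDATA in 382 rows of each table, and FAIL in 2, 5 and 5 rows of leukaemias 1, 2 and 3, which were listed at 0. Genes that most cells use were among those at 0, such as the RNA-binding protein gene Hnrnpd in all 3 leukaemias, so an exact 0 is reported as listed at 0 and not as absence. All rows were kept whatever their status, as planned. Coordinates are the tables' own, with 1 added to each start, because 64.1% of starts were 1 below those of the RefSeq genes of GRCm38, the assembly that mm10 names, and 3.18% were equal.

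FPKM summed to 431407, 416284 and 424595 in leukaemias 1, 2 and 3. The number of fragments per library is not given in the sources used here. Read as 2 Poisson SDs to either side, the deposited intervals imply 26404013, 24865466 and 27996991 fragments over genes. These implied counts were not whole: of values under 200, 12.6%, 12.1% and 13.4% lay within 0.05 of a whole number, where 10% would by chance. They are therefore given only as the scale of the depth. FPKM lay above its own upper bound in 2739, 2778 and 2786 rows with FPKM of at least 1, by a median of 1.05 times in leukaemia 1, so that FPKM and its bounds are not on 1 scale for these genes. Intervals cover counting and assignment of fragments, not differences between animals.

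From these values log2(FPKM + 1) was computed, a scale that understates differences of low genes. The lists were those of the 24 groups described in the results. These lists, the rule for named genes, the tests and the alternatives not marked as added were fixed before the data were examined. For each list the median per leukaemia was given with its percentile among 10000 random lists of the same size, drawn from genes with FPKM of at least 0.1 in any leukaemia. The difference of the pan-B and T cell medians was tested over the 3 leukaemias with an exact two-sided sign-flip permutation test. For each of the 3 pairs, genes were counted that differed by at least 1 on the log2 scale, had FPKM of at least 1 in either leukaemia and had deposited intervals that did not overlap. List differences between pairs were median member differences, the medians of the differences of single members in the background and not gaps between list medians, with percentiles among 10000 random lists matched on mean log2(FPKM + 1) in 20 bins. Correlations ran across genes with FPKM of at least 1 in any leukaemia.

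The text names Spi1, Spib and Cd79a, and the 3 members of highest mean FPKM of each list. The lowest member is named for pathway lists and for the pan-B, pro-B and pre-B, mature B, T cell and myeloid lists. It also names members that differed in a pair, the 5 genes furthest above and below both other leukaemias with FPKM of at least 5 in 1 of them, and the 10 genes of highest mean FPKM. Ribosomal, mitochondrial and unnamed genes were left out of the genes ranked as furthest from both others. Some genes that this rule names are not reported here. The older symbols Igj and Faim3 were read as Jchain and Fcmr, and Ighd and Hbb-b2 were not analysed here. Immunoglobulin and T cell receptor segments were not analysed here, so the planned comparison of segment use was not made.

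Calls were tested on simulated data for 2 leukaemias with counting error only, over 9960 genes. Of 50 genes each changed by 1.5, 2.5, 4 and 8 times, 0, 43, 48 and 50 were called, and of 9760 unchanged genes 0 were. Simulated intervals were centred on their values, unlike those of genes whose FPKM exceeded its upper bound. These counts therefore do not test the interval criterion for such genes. Of 500 random lists of 12 genes, 6% fell outside percentiles 2.5 to 97.5 of matched lists, and all 100 lists raised by 1 on the log2 scale did. The alternatives tried were other pseudocounts, filters and thresholds, 2 rescalings of FPKM, only rows of status OK, each library left out in turn, and list means. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.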

Results

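Gene expression was measured by RNA sequencing in 3 thymic leukaemias of diseased Mb1-CreDPB mice on the C57BL/6 background. In this model Cre recombinase, expressed from the mb-1 (Cd79a) locus, deletes Spi1, the gene of the ETS transcription factor PU.1, in B lineage cells of mice that also lack the related factor Spi-B (Spib). The libraries formed 1 group and are called here leukaemia 1 (Thy_853), leukaemia 2 (Thy_854) and leukaemia 3 (Thy_857). The labels give a number of its own to each thymus but do not state in words that each came from another mouse, so the spread over n = 3 is that between these libraries. No control samples were analysed here. Every ± below is an SD over the 3 leukaemias. Values given in threes are for leukaemias 1, 2 and 3 in that order, unless pairs are named. For single genes they are FPKM (fragments scaled to transcript length and to the fragments of the library). List medians are on the log2(FPKM + 1) scale unless FPKM is named. FPKM of at least 1 was reached by 9992, 9797 and 9706 genes, and by 9300 genes in all 3 leukaemias, which are called expressed here. The median deposited 95% interval of genes at this level extended 5.49%, 5.62% and 5.34% to either side of its midpoint.

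The genes the model targets were read first. Spi1 transcripts were listed in every leukaemia, at 11.6, 6.70 and 7.13 FPKM, a mean of 8.47 ± 2.69. Spib stood at 11.8, 14.6 and 9.60 FPKM, a mean of 12.02 ± 2.53. Cd79a, which encodes a signalling chain of the B cell receptor and hosts Cre in this model, was far more abundant at 669, 715 and 486 FPKM (623 ± 121). These Cd79a values lay above its deposited upper bounds of 581, 615 and 424. In mm10 coordinates Spi1 lies on chromosome 2, 91096678 to 91115759, Spib on chromosome 7, 44525995 to 44532071 and Cd79a on chromosome 7, 24897511 to 24902197. None of the 3 genes met the criteria used below for single genes in any pair of leukaemias. Lists were compared between leukaemias by the median member difference, which is the median over their members of each gene's difference in log2(FPKM + 1) and can depart from the gap between list medians. For the 3 targeted genes it was 0.56 for leukaemia 2 minus 3, at percentile 99.62 of expression-matched random lists, although Spi1 itself differed by -0.08. With list means targeted 2 minus 3 was 0.35, inside percentiles 2.5 to 97.5. The median member differences of -0.10 for leukaemia 1 minus 2, where the mean was 0.11, and 0.46 for 1 minus 3 lay at percentiles 33.5 and 95.9. Measured the same way, the median T cell gene stood at 11.1, 2.84 and 2.75 FPKM and the median myeloid gene, of a lineage that also expresses Spi1, at 6.82, 6.05 and 3.20. The median of the 3 targeted genes was 3.68 ± 0.28 on the log2(FPKM + 1) scale, at percentiles 62.3, 70.2 and 54.95 of random lists of the same size. Exons outside a deletion also enter the FPKM of a gene, so these values do not check the deletion.

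The leukaemias were compared for B and T lineage transcripts, since they grew in the thymus, the organ in which T cells form. B lineage genes were abundant. Vpreb3, a surrogate light chain partner, reached 1207 ± 279.8 FPKM, Cd79a 623 ± 121 and Cd79b, its partner chain, 556 ± 137. In each leukaemia the FPKM of Vpreb3 and Cd79a lay above their deposited upper bounds, which for Vpreb3 were 1055, 762 and 684. Of the pan-B genes 11 of 12 were expressed, and the exception was Blk, a Src family kinase, at 0.727, 33.9 and 22.3 FPKM. The pan-B median was 7.92 ± 0.24 on the log2(FPKM + 1) scale and lay above all 10000 random lists of the same size in each leukaemia. The T cell median was 2.48 ± 0.97. The pan-B median exceeded the T cell median by 4.60, 5.80 and 5.93 in leukaemias 1, 2 and 3, a mean of 5.44 ± 0.73 (n = 3; exact two-sided sign-flip permutation test, p = 0.25). That is the smallest p this test can give with 3 libraries.

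Transcripts of the surrogate light chain of the pre-B cell receptor were abundant. Its genes Igll1 and Vpreb1 stood at 2528 ± 593 and 1699.6 ± 423 FPKM, and Vpreb2, a near copy of Vpreb1 with which it can share reads, at 375 ± 112. In each leukaemia the FPKM of these genes lay above their deposited upper bounds, which for Vpreb2 were 270, 232 and 146. The interleukin 7 receptor gene Il7r reached 104 ± 30.8 FPKM and the peptidase gene Enpep, which encodes the BP-1 antigen of early B cells, 262 ± 87.6. The recombinase gene Rag1 was at 12.7, 0.511 and 1.70 FPKM, Rag2 at 3.15, 0.0678 and 0.105 and Dntt, which encodes terminal transferase, at 2.66, 0.187 and 0.310. The lowest member was Kit, a receptor of early progenitors, at 0.282, 0.127 and 0.0585 FPKM. Of the pro-B and pre-B list, 8 of 13 members were expressed, with a median of 6.35 ± 0.28 at percentiles 100, 99.98 and 100 of random lists.

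Genes of later B cell stages were unevenly expressed. The mature B list had 6 of 13 expressed members and a median of 1.11 ± 0.09, at percentiles 1.11, 2.17 and 2.09 among genes with FPKM of at least 0.1. Against all listed genes the mature B percentile was 77.7 as a mean over the leukaemias, so its place below percentile 2.5 holds only against the narrower background. Its highest members were class II antigen presentation genes, with H2-Ab1 at 81.2 ± 3.37 and H2-Aa at 42.3 ± 21.5 FPKM, and Cd74 at 137, 45.3 and 60.2 FPKM in leukaemias 1, 2 and 3. The IgM receptor gene Fcmr, its lowest member, was listed at 0, 0.0258 and 0 FPKM. Of the plasma cell list, 4 of 7 members were expressed, with a median of 2.44 ± 0.57 at percentiles 11.9, 40.1 and 31.8. Mzb1, an endoplasmic reticulum cofactor of immunoglobulin assembly, reached 606 ± 98.6 FPKM, Irf4 117 ± 25.04 and Xbp1 25.6 ± 3.33.

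Lists of other cell types that a thymus can hold had medians below the pan-B and the pro-B and pre-B medians. The T cell median lay at percentiles 70.1, 8.12 and 8.13 in leukaemias 1, 2 and 3, and 9 of 15 T cell genes were expressed. Zap70, a kinase of antigen receptor signalling, was the highest at 123 ± 11.9 FPKM, followed by Cd3g at 41.8, 9.83 and 8.97 and Cd8b1 at 19.8, 4.02 and 6.71. Ptcra, which encodes the pre-T cell receptor alpha chain, was listed at 0.0887, 0 and 0.0538 FPKM. NK cell genes had a median of 1.63 ± 0.88, at percentiles 30.1, 4.25 and 8.40, led by Gzma at 17.1, 125 and 62.6, Nkg7 at 59.9, 15.5 and 16.1 and Klrd1 at 5.91, 1.48 and 2.57 FPKM. Myeloid genes had a median of 2.62 ± 0.48, at percentiles 37.6, 33.5 and 10.9. S100a8 and S100a9, neutrophil calcium-binding proteins, stood at 117, 92.1 and 13.8 and at 96.6, 68.3 and 11.7 FPKM, the complement gene C1qb at 61.8, 38.1 and 27.5, and Cd14, the lowest, at 1.20, 0.240 and 0.167. The FPKM of S100a8 lay above its deposited upper bounds of 66.04, 50.8 and 9.25.

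Erythroid, dendritic, epithelial and stromal genes had low medians, with globins and Pecam1 higher. The erythroid median was 0.35, 0.97 and 0.09 on the log2(FPKM + 1) scale, at percentiles 0.08, 2.08 and 0. The protocol had included lysis of red cells. Globin transcripts remained, with Hba-a2 at 72.5, 88.95 and 14.1, Hbb-b1 at 39.2, 54.95 and 7.87 and Hbb-bt at 24.4, 36.4 and 4.19 FPKM. Globin genes are near copies that can share reads. The dendritic median was 0.16 ± 0.08, at percentiles 0.11, 0.01 and 0.17, with Itgax at 2.06 ± 1.08, Zbtb46 at 0.201 ± 0.118 and Xcr1 at 0.125 ± 0.0436 FPKM. The thymic epithelium median was 0.10 ± 0.03, at percentiles 0, 0 and 0.01, and its highest members Ccl25, Prss16 and Cldn4 reached 2.27 ± 0.317, 2.21 ± 1.19 and 1.11 ± 0.139 FPKM. In the stroma and endothelium list the median was 0.70 ± 0.27, at percentiles 1.29, 0.79 and 0.37. Pecam1, an adhesion molecule of endothelium and of several leukocytes, stood at 37.04 ± 12.8 FPKM, and the collagen genes Col3a1 and Col1a1 at 1.55 ± 0.469 and 1.35 ± 0.553. Against all listed genes, of which more are unexpressed, the mean percentiles over the leukaemias lay inside 2.5 to 97.5, with an erythroid percentile of 62.5, dendritic percentile of 41.4, thymic epithelium percentile of 50.9 and stroma and endothelium percentile of 64.6.

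**Figure D1:**
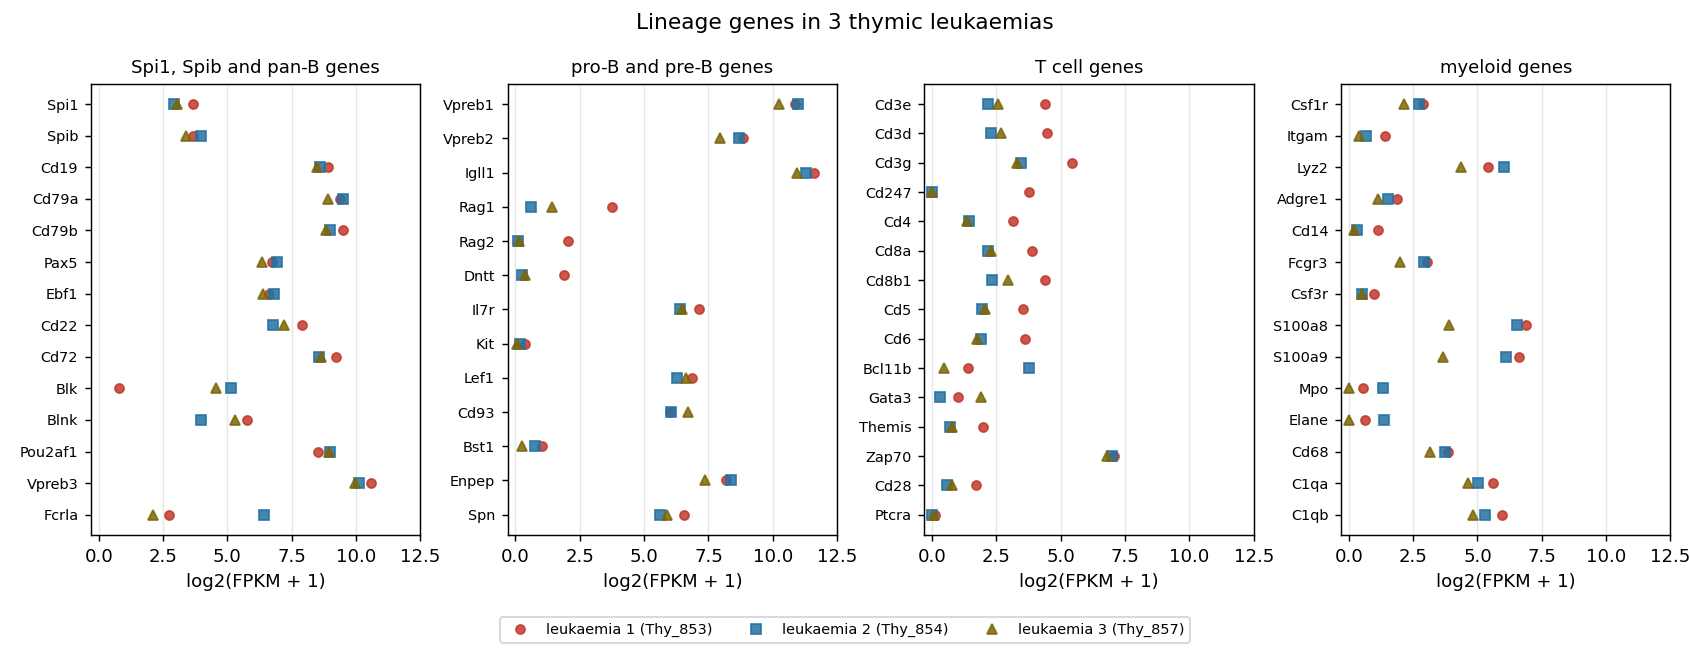
Each point is 1 gene in 1 leukaemia, with log2(FPKM + 1) on the horizontal axes and genes on the vertical axes, in panels for Spi1, Spib and pan-B genes, pro-B and pre-B genes, T cell genes and myeloid genes. Rag1 and most T cell genes lie to the right in leukaemia 1 and Blk to the left, whereas Zap70 is high in all 3, at 132, 126 and 109 FPKM.

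ETS family and B cell receptor signalling genes were read next, since Spi1 and Spib encode ETS factors. Ets1 stood at 166 ± 15.2 FPKM, Elf1 at 54.6 ± 4.15 and Fli1 at 39.5 ± 4.13, and the lowest family member, Erg, at 0.0718, 0.153 and 0.415 in leukaemias 1, 2 and 3. Of the ETS genes 12 of 15 were expressed, and the list median was 3.36 ± 0.19, at percentiles 65.6, 50.1 and 62.8. B cell receptor signalling genes lay higher, with 13 of 14 expressed and a median of 4.84 ± 0.25, at percentiles 99.75, 98.5 and 98.1. Plcg2, a phospholipase, reached 107 ± 11.2 FPKM, Vav1 64.8 ± 3.93 and the kinase gene Prkcb 62.03 ± 4.28.

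Cytokine signalling, leukaemia, Notch and apoptosis genes completed the signalling lists. All 17 cytokine and JAK-STAT genes were expressed, with a median of 4.11 ± 0.14 at percentiles 86.6, 93.7 and 93.1. Socs2, a feedback inhibitor of cytokine receptors, stood at 109 ± 12.7 FPKM, Il7r at 104 ± 30.8, the shared cytokine receptor chain Il2rg at 62.5 ± 7.87 and Socs3, the lowest, at 2.26 ± 0.887. Genes linked to leukaemia had a median of 4.29 ± 0.08, at percentiles 95.3, 95.5 and 96.8, and 14 of 18 were expressed. Myb led this list at 200.1 ± 45.3 FPKM, ahead of Trp53 at 135 ± 14.3, and Mycn was listed at 0.00671, 0.00695 and 0. Of the Notch list 4 of 7 members were expressed, with a median of 1.23 ± 0.25 at percentiles 8.70, 5.77 and 6.11. The Notch target Hes1 stood at 40.6 ± 6.92 FPKM, Nrarp at 6.80 ± 2.71, Notch1 at 4.78 ± 0.946 and Notch3 at 0.0354 ± 0.0198. Apoptosis genes had a median of 4.39 ± 0.12, at percentiles 90.3, 93.7 and 93.7, and 9 of 10 were expressed. Bax, Mcl1 and Bak1 stood at 115 ± 9.94, 82.7 ± 12.3 and 73.1 ± 8.35 FPKM, and Bcl2, the survival factor, was the lowest at 0.867 ± 0.348.

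Cell division genes were high throughout. All 20 proliferation genes were expressed, with a median of 6.36 ± 0.48 above all random lists in each leukaemia. The replication genes Pcna, Rrm2 and Mcm7 stood at 323 ± 111, 163 ± 51.4 and 152 ± 46.5 FPKM, and Bub1, a mitotic checkpoint kinase, at 13.7 ± 4.86. In the list of hypermutation and base editing genes, whose median was 5.10 ± 0.35 at percentiles 95.8, 98.8 and 99.19, 7 of 8 were expressed. The cytidine deaminase genes Apobec3 and Apobec1 reached 183 ± 37.1 and 90.3 ± 28.8 FPKM and the mismatch repair gene Msh6 39.9 ± 6.89.

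Stress, interferon, housekeeping and sex-linked genes were measured alongside. The immediate early and stress median was 2.87 ± 0.55, at percentiles 56.9, 41.6 and 18.9, with 8 of 10 expressed. The heat shock genes Hspa1b and Hspa1a, which are near copies, stood at 71.6 ± 14.3 and 39.2 ± 6.87 FPKM, Ier2 at 36.5 ± 1.16 and Fosb at 0.278 ± 0.0885. The interferon median was 3.57 ± 1.25, at percentiles 98.98, 35.9 and 38.8, and 9 of 10 were expressed. Isg15 and Irf7 stood at 116, 55.5 and 46.6 and at 103, 35.5 and 21.2 FPKM, and Rsad2 was lowest at 5.16, 1.91 and 0.511. All 10 housekeeping genes were expressed, with a median of 7.59 ± 0.05 above all random lists in each leukaemia, led by B2m at 2710.4 ± 598, Actb at 1476 ± 117 and Ppia at 1214 ± 243 FPKM, with Tbp lowest at 22.2 ± 1.82. The sex-linked median was 2.36 ± 0.18, at percentiles 21.97, 31.2 and 28.9. Xist, transcribed from the inactive X chromosome, was at 0.122, 0.185 and 0.120 FPKM, and the Y-linked Ddx3y, Eif2s3y and Kdm5d at 11.3, 14.9 and 10.3, at 3.50, 45.00 and 4.26 and at 0.476, 4.73 and 5.40.

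Among the 10 genes of highest mean FPKM were Eef1a1, Crip1, Rpl41, Mir703, Rplp1, B2m, Rps14, Ptma and Igll1. Eef1a1, a translation elongation factor, stood at 5499 ± 451 FPKM, Crip1 at 3799 ± 1568, and Ptma at 2610.1 ± 567. The ribosomal protein genes Rpl41, Rplp1 and Rps14 lay between 2649.9 ± 390.0 and 3561 ± 72.2 FPKM. Mir703, a microRNA gene on chromosome 5, 98475556 to 98475664, was listed at 2814 ± 432 FPKM, but the midpoints of its deposited intervals were 28.02, 22.5 and 26.04. Those of Crip1 were 3193, 1455 and 1832. FPKM exceeded the upper bound of its own interval in 27.3%, 28.2% and 28.6% of loci with FPKM of at least 1, so the level of such a gene depends on which deposited value is read.

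The leukaemias were then compared with each other. Leukaemias 2 and 3 were the closest pair, with a Spearman correlation of 0.961 and a Pearson correlation of 0.960 across 10412 genes, which are not independent replicates. The corresponding values were 0.939 and 0.937 for leukaemias 1 and 2, and 0.933 and 0.931 for leukaemias 1 and 3, and no pair held identical values. Genes were counted as differing when they lay at least 1 apart on the log2(FPKM + 1) scale, reached FPKM of at least 1 in either leukaemia and had intervals that did not overlap. By these criteria 572 genes were higher in leukaemia 1 than in leukaemia 2 and 268 lower. Against leukaemia 3, 693 genes were higher in leukaemia 1 and 331 lower. Between leukaemias 2 and 3, 297 genes were higher in leukaemia 2 and 173 in leukaemia 3. Genes listed at 0 in 1 leukaemia of the pair, which is not read as absence, were part of each total. They made up 70 of 840 for leukaemias 1 and 2, 72 of 1024 for 1 and 3 and 60 of 470 for 2 and 3. With 1 library per leukaemia these differences have no replicate check, the intervals cover counting and assignment of fragments only, and no p-value is given. These counts, which in the order given were 572, 268, 693, 331, 297 and 173, depended on the settings. They were 879, 412, 1000, 510, 441 and 260 with a pseudocount of 0.1 and 907, 438, 1031, 527, 458 and 277 with a pseudocount of 0.01. With FPKM of at least 5 in either leukaemia they were 409, 177, 468, 258, 182 and 105, and with a threshold of 2 on the log2 scale 96, 73, 122, 58, 79 and 39.

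T cell, NK cell and interferon genes set leukaemia 1 apart. Of the 15 T cell genes, 11 were higher in leukaemia 1 than in leukaemia 2, 1 was lower and 3 did not differ by the criteria. The median member difference was 1.69 against leukaemia 2 and 1.53 against leukaemia 3, both above all 10000 expression-matched random lists. The genes higher in leukaemia 1 than in both others were Cd3e (20.1, 3.51 and 4.87 FPKM), Cd3d (21.01, 3.86 and 5.43), Cd3g, Cd4 (7.79, 1.72 and 1.54), Cd8a (13.8, 3.53 and 3.92), Cd8b1, Cd5, Cd6, Themis and Cd247, and Cd28 was higher than in leukaemia 2. Cd247, the zeta chain of the T cell receptor complex, was listed at 0 in leukaemias 2 and 3. Bcl11b, a T lineage transcription factor, was higher in leukaemia 2 than in both others at 1.61, 12.7 and 0.378 FPKM, Gata3 was higher in leukaemia 3 than in leukaemia 2 at 1.02, 0.227 and 2.75, and Zap70 did not differ. Among the NK cell genes Prf1, Eomes and Nkg7 were higher in leukaemia 1 than in both others and Klrd1 than in leukaemia 2, with median member differences of 1.45 and 0.96 at percentiles 100 and 99.96. Gzma, a granzyme gene, was lower in leukaemia 1 at 17.1, 125 and 62.6 FPKM. With list means the difference named NK cell 1 minus 3 was 0.55, inside percentiles 2.5 to 97.5 of random lists.

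Interferon-induced genes were higher in leukaemia 1 as a group. Of the 10 listed, 8 were higher than in leukaemia 2 and 9 than in leukaemia 3, with none lower. The median member differences of 1.24 and 1.91 lay above all matched random lists, in the leukaemia whose median member differences were also 1.69 and 1.53 for T cell and 1.45 and 0.96 for NK cell genes. The widest gap was that of Oas1a, an antiviral synthetase gene, at 81.8, 5.87 and 8.88 FPKM. Mx1 stood at 13.01, 3.99 and 2.63, Ifit1 at 5.74, 1.56 and 1.004, Ifit3 at 11.98, 5.35 and 2.33 and Oasl2 at 19.3, 6.23 and 4.54. Irf7, Isg15 and Rsad2 were higher than in both others, and Usp18 (50.6, 30.8 and 16.1) than in leukaemia 3. No interferon gene differed between leukaemias 2 and 3, although their median member difference of 0.42 lay at percentile 99.96. The interferon list medians of these leukaemias, 2.82 and 2.89, stood the other way.

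B lineage genes also varied between the leukaemias. Rag1, Rag2 and Dntt were higher in leukaemia 1 than in both others, by 3.18, 1.96 and 1.62 against leukaemia 2, while the other 10 pro-B and pre-B genes met the criteria in neither comparison. Thymocytes also express Rag1, Rag2 and Dntt, and the median member difference of the T cell list in the same leukaemia was 1.69 against leukaemia 2 and 1.53 against leukaemia 3. Ptcra of that list, the pre-T cell receptor alpha chain gene, was at 0.0887, 0 and 0.0538 FPKM and met the criteria in no pair. The median member difference of the pro-B and pre-B list, leukaemia 1 minus 2 and 1 minus 3, was 0.33 and 0.68, at percentiles 99.42 and 100, and Enpep was higher in leukaemia 2 than in leukaemia 3. Blk was lower in leukaemia 1 than in both others, as were Ms4a1, which encodes CD20, at 1.07, 9.76 and 16.5 FPKM and the J chain gene Jchain at 0.262, 6.43 and 5.22. The receptor-like gene Fcrla was higher in leukaemia 2 at 5.66, 84.1 and 3.32 FPKM. Cd22 and Blnk were higher in leukaemia 1 than in leukaemia 2, at 235, 107 and 146 and 53.9, 14.6 and 37.9 FPKM, and Blnk also in leukaemia 3 than in leukaemia 2. Cd74, H2-Aa and H2-Eb1, which myeloid and dendritic cells also express, were higher in leukaemia 1 than in both others. The median member difference of the myeloid list was 0.35 and 0.94 for leukaemia 1 against the others. The pan-B median member difference was 0.11, 0.48 and 0.16 for leukaemias 1 minus 2, 1 minus 3 and 2 minus 3, at percentiles 88.4, 99.95 and 99.80. With list means pan-B 1 minus 3 was 0.0799, inside percentiles 2.5 to 97.5, and pan-B 1 minus 2 was -0.34, of the other sign. The pan-B list medians of leukaemias 2 and 3, 7.74 and 7.84, stood the other way from the median member difference. The plasma cell median member difference was -0.36 for leukaemia 1 minus 2, at percentile 1.95, and 0.35 for leukaemia 2 minus 3, at percentile 99.50. With list means plasma cell 2 minus 3 was 0.20, inside percentiles 2.5 to 97.5.

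The proliferation median was lowest in leukaemia 1 and highest in leukaemia 3, at 5.94, 6.24 and 6.88 on the log2(FPKM + 1) scale. The median member differences were -0.46 for leukaemia 1 minus 2, -0.93 for 1 minus 3 and -0.36 for 2 minus 3, each below all matched random lists. Of the 20 genes 15 differed in no pair by the criteria. T cell, NK cell and myeloid markers moved the opposite way to this list in leukaemia 1. Against leukaemias 2 and 3, their median member differences were 1.69 and 1.53 for T cell and 1.45 and 0.96 for NK cell genes. Those for myeloid genes were 0.35 and 0.94. The erythroid list moved the same way as proliferation against leukaemia 2, at -0.52, and stood at 0.20 against leukaemia 3. The stroma and endothelium list stood at 0.03 and 0.68. Of the T cell, NK cell and myeloid lists, only myeloid, at 0.60, had the opposite sign to proliferation for leukaemia 2 minus 3. The erythroid and the stroma and endothelium lists, at 0.83 and 0.41, also had the opposite sign. In that pair the T cell and NK cell differences were -0.08 and -0.23, at percentiles 25.2 and 2.63. The myeloid median was lowest in leukaemia 3. Mcm2, a replication licensing gene, was lower in leukaemia 1 than in both others at 57.9, 132 and 123 FPKM, and Ccna2, Pcna, Mcm3 and Aurkb were lower in leukaemia 1 than in leukaemia 3. Pcna stood at 209, 333 and 429 FPKM. Ung, the uracil glycosylase gene, was lower in leukaemia 1 than in both others at 14.6, 34.9 and 34.8 FPKM.

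The myeloid median and 4 globin genes were lowest in leukaemia 3, with myeloid medians of 2.96, 2.82 and 2.07 on the log2(FPKM + 1) scale. The myeloid median member differences were 0.35, 0.94 and 0.60 for leukaemias 1 minus 2, 1 minus 3 and 2 minus 3, at percentiles 98.5, 100 and 100. S100a8, S100a9 and Lyz2 (41.7, 64.3 and 19.3 FPKM) were lower in leukaemia 3 than in both others, Mpo and Elane, the last listed at 0 in leukaemia 3, than in leukaemia 2, and Fcgr3 and C1qb than in leukaemia 1. Hba-a2, Hbb-b1 and Hbb-bt were lower in leukaemia 3 than in both others, and Hba-a1, listed at 6.69, 28.9 and 0 FPKM, differed in every pair. The other 7 erythroid genes differed in none. The erythroid median member differences were -0.52 for leukaemia 1 minus 2 and 0.83 for 2 minus 3, at percentiles 0.01 and 100. For leukaemia 1 minus 3 the erythroid median member difference was 0.20 at percentile 81.8, inside the range of random lists, so only the globins met a criterion in that pair. Erythroid 1 minus 3 was 1.04 with list means, 1.10 with a pseudocount of 0.1 and 2.34 with a pseudocount of 0.01, each above percentile 97.5. Pecam1 was higher in leukaemia 2 than in leukaemia 3, and the stroma and endothelium median member differences of 0.68 for leukaemia 1 minus 3 and 0.41 for 2 minus 3 lay at percentiles 99.16 and 99.54 over the 7 members in the background. Myeloid 1 minus 2, in which no member met the criteria, and both stroma and endothelium differences lay inside percentiles 2.5 to 97.5 with list means and with a pseudocount of 0.01, and so did the first and the stroma and endothelium 1 minus 3 difference with a pseudocount of 0.1.

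In the signalling lists single genes differed. Ets2 was higher in leukaemia 2 than in both others at 2.41, 6.72 and 1.21 FPKM, as was Il2ra, a chain of the interleukin 2 receptor, at 3.55, 17.2 and 1.96. Pik3ap1, an adaptor of B cell receptor signalling, was higher in leukaemia 1 than in both others at 36.02, 11.8 and 17.1 FPKM, whereas Fcgr2b and Cish were higher in leukaemia 2 than in leukaemia 3. Fos and Jun were higher in leukaemia 1 than in leukaemia 3, at 13.7, 10.3 and 2.80 and 4.73, 3.01 and 1.12 FPKM, and Fos was also higher in leukaemia 2 than in leukaemia 3. For leukaemia 1 minus 3 the median member differences of the cytokine JAK-STAT and leukaemia lists were 0.34 and 0.22, at percentiles 99.83 and 97.7. The list medians themselves were lower in leukaemia 1 than in leukaemia 3, at 3.95 and 4.19 for cytokine JAK-STAT genes and 4.24 and 4.39 for leukaemia genes. The immediate early and stress median member difference was 0.40 for leukaemia 1 minus 2, at percentile 99.13. No member of these 3 lists met the criteria in the pair named. The B cell receptor signalling median member difference was 0.11 for leukaemia 2 minus 3, at percentile 98.6. With list means these 4 differences lay inside percentiles 2.5 to 97.5, as did those of the leukaemia and the immediate early and stress lists with a pseudocount of 0.1 or 0.01. No member of the apoptosis, Notch, housekeeping, thymic epithelium, dendritic or leukaemia lists differed in any pair. The dendritic median member difference was 0.21 for leukaemia 1 minus 2 and -0.11 for 2 minus 3, at percentiles 97.52 and 0.95, and both lay inside 2.5 to 97.5 with list means. The sex-linked median member differences were -0.37 and 0.49 in these pairs, at percentiles 2.48 and 99.50, and both lay inside with a pseudocount of 0.01. Of these, dendritic 1 minus 2 also lay inside with genes above 0 in both only and with interval midpoints, 2 settings chosen after the values were seen, dendritic 2 minus 3 with a pseudocount of 0.01, and sex-linked 1 minus 2 with a pseudocount of 0.1, median-of-ratios factors and interval midpoints. Of 72 median member differences, 32 lay outside percentiles 2.5 to 97.5 of matched random lists, where 3.6 would by chance. Genes of 1 programme vary together, so these percentiles describe the libraries and are not p-values.

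**Figure D2:**
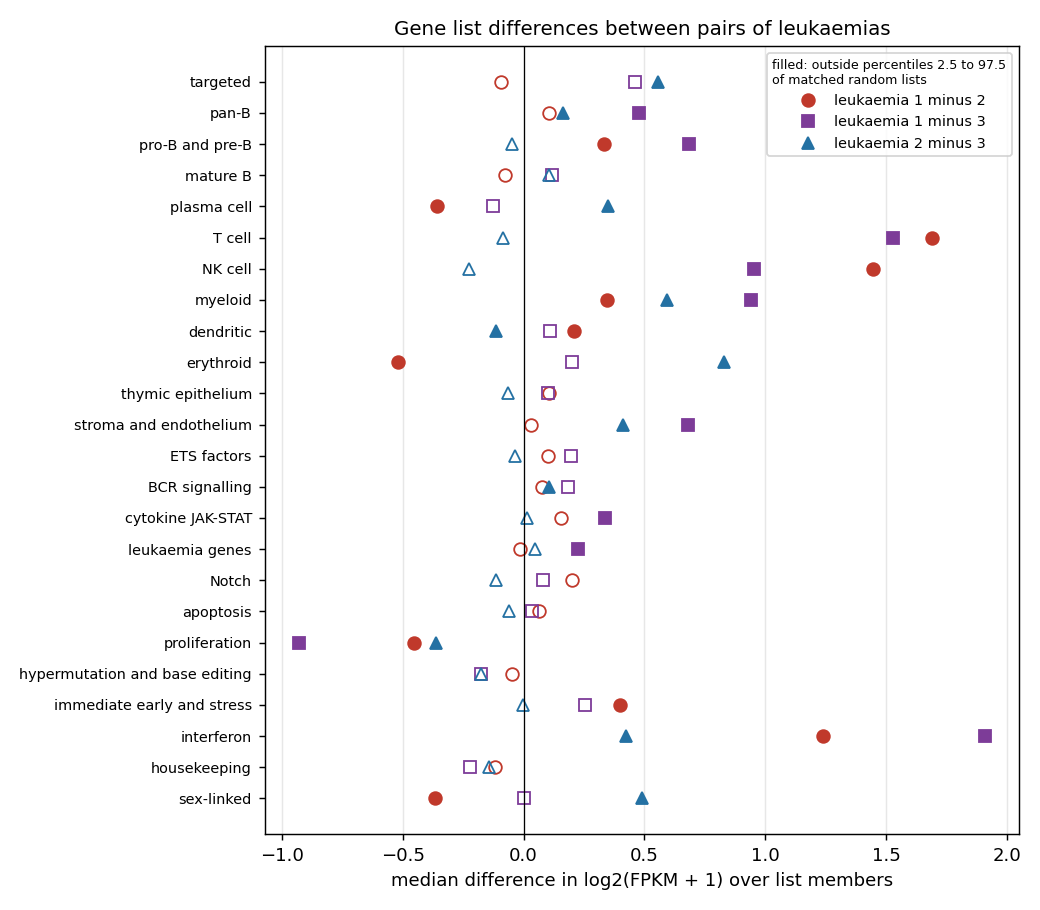
Each point is the median member difference in log2(FPKM + 1) over the members of 1 fixed list between 2 leukaemias, and filled points lie outside percentiles 2.5 to 97.5 of 10000 expression-matched random lists. T cell and interferon lists reach 1.69 and 1.91 in leukaemia 1 against the others, and proliferation reaches -0.93 for leukaemia 1 minus 3.

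Genes that set 1 leukaemia apart from both others were ranked by the smaller of their differences. In leukaemia 1, 367 genes were higher than in both others and 109 lower, in leukaemia 2 112 and 84, and in leukaemia 3 63 and 138. The first 5 higher in leukaemia 1 were Ddit3, Cog4, Atf5, Cd247 and Rpain, each listed at 0 in leukaemias 2 and 3 and at 20.6, 17.7, 12.96, 12.4 and 12.3 FPKM in leukaemia 1. Ddit3 and Cog4 overlap the loci of Mars and Sf3b3. The first 5 lower there were Ifi27, Cmc1, Aff1 and Pigf, listed at 0 in leukaemia 1 with Aff1 marked as a failed estimate, and Blk. Mxd3 was listed at 0 in leukaemias 1 and 2 and at 25.2 FPKM in leukaemia 3. The first 5 lower in leukaemia 2 (Srsf5, Eftud2, Eif3j1, Eif3j2 and Sdr39u1) and in leukaemia 3 (Chtop, Cep250, Mea1, Toporsos and Gvin1) were listed at 0 there, and the estimates of Srsf5, Eftud2, Eif3j1, Chtop, Cep250 and Gvin1 were marked as failed. No fold is given against a value listed at 0.

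Genes with values above 0 in all 3 were therefore read as well, a choice made after the values were seen. In leukaemia 1 Hnrnpll, a splicing regulator, stood at 40.8, 2.95 and 1.23 FPKM, Rgs10 at 267, 35.1 and 36.6 and Wfdc13 at 52.7, 4.54 and 0.208, beside Oas1a. Lower there, besides Blk, were the connexin gene Gja1 (1.37, 28.6 and 25.6), Acat1 (1.86, 34.8 and 28.4), Tmem223 (7.53, 58.9 and 59.3) and Ttll12 (1.47, 17.6 and 15.1). Leukaemia 2 had the calcium channel gene Cacna1h at 0.0522, 19.7 and 0.0479 FPKM, the receptor kinase gene Mst1r at 0.131, 14.95 and 0.0195, Kcne1 at 0.854, 20.1 and 0.467 and Wnt10a at 0.0729, 12.4 and 0.247, beside Fcrla, all named by the original ranking. Lower there were Dmrta2 (19.3, 2.02 and 15.6), Bex3 (16.3, 2.16 and 20.4), Psrc1 (9.29, 1.04 and 10.5), Dnph1 (15.4, 2.32 and 21.4) and Plpp2 (6.21, 0.678 and 6.45). Leukaemia 3 had Myl10 at 0.398, 1.93 and 29.3 FPKM and Oaf at 0.742, 2.90 and 38.5, both named by the original ranking, and the imprinted transcript H19 at 0.0770, 0.0559 and 8.12, the N-cadherin gene Cdh2 at 0.0173, 0.0233 and 7.27 and Prodh at 1.42, 1.05 and 13.7. Lower there were the neutrophil granule genes Ngp (11.6, 19.1 and 0.616) and Lcn2 (11.9, 10.3 and 0.799), the lens filament gene Bfsp2 (102, 116 and 13.8), Sytl2 (28.7, 29.8 and 3.29) and S100a8.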

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

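All alternatives were planned, except the interval midpoint in place of FPKM and the limit to genes above 0 in both leukaemias, which were chosen after seeing the data. No difference past its criterion changed sign under the alternatives run. Of 72 list differences, 57 stayed on the same side of percentiles 2.5 and 97.5 with list means, 65 with a pseudocount of 0.1 and 62 with a pseudocount of 0.01. In these counts a difference that had lain inside and went outside with the other sign would also count as staying. The rescaling factors lay between 0.982 and 1.019 and hardly move a gene, and a mean over 3 libraries cannot move by its SD when 1 is left out, so neither says that gene levels are stable. Deposited intervals bound counting and assignment only.

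With each library left out in turn, Spi1 mean FPKM ranged from 6.92 to 9.35, Spib mean FPKM from 10.7 to 13.2 and the B minus T marker difference from 5.20 to 5.87. That difference was 4.87 with list means and 5.77 with a pseudocount of 0.01.

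Counts of differing genes moved by over 1.5 times as follows, by the construction of each setting. For genes higher in leukaemia 1 than in leukaemia 2 the count was 879 with a pseudocount of 0.1, 907 with a pseudocount of 0.01 and 96 with a threshold of 2 on the log2 scale. The genes higher in leukaemia 2 than in leukaemia 1 numbered 412 with a pseudocount of 0.1, 438 with a pseudocount of 0.01, 177 with FPKM of at least 5 in either leukaemia and 73 with a threshold of 2 on the log2 scale. For genes higher in leukaemia 1 than in leukaemia 3 the count was 122 with a threshold of 2 on the log2 scale. The genes higher in leukaemia 3 than in leukaemia 1 numbered 510 with a pseudocount of 0.1, 527 with a pseudocount of 0.01 and 58 with a threshold of 2 on the log2 scale. For genes higher in leukaemia 2 than in leukaemia 3 the count was 458 with a pseudocount of 0.01, 182 with FPKM of at least 5 in either leukaemia and 79 with a threshold of 2 on the log2 scale. The genes higher in leukaemia 3 than in leukaemia 2 numbered 260 with a pseudocount of 0.1, 277 with a pseudocount of 0.01, 105 with FPKM of at least 5 in either leukaemia and 39 with a threshold of 2 on the log2 scale.

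Correlations moved by more than their spread between pairs, by the choice of genes or the pseudocount. The Spearman correlation of leukaemias 1 and 2 was 0.916 with FPKM of at least 5. The Pearson correlation of leukaemias 1 and 2 was 0.899 with a pseudocount of 0.1, 0.980 with no filter and 0.910 with FPKM of at least 5. The Spearman correlation of leukaemias 1 and 3 was 0.948 with no filter and 0.906 with FPKM of at least 5. The Pearson correlation of leukaemias 1 and 3 was 0.892 with a pseudocount of 0.1, 0.978 with no filter and 0.898 with FPKM of at least 5. The Pearson correlation of leukaemias 2 and 3 was 0.928 with a pseudocount of 0.1, 0.987 with no filter and 0.942 with FPKM of at least 5.

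With a pseudocount of 0.1, list medians of low genes moved by more than their spread, by construction: mature B median 0.33, dendritic median -2.25, erythroid median -1.31, thymic epithelium median -2.55, stroma and endothelium median -0.57, Notch median 0.51, sex-linked median 2.08.

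Against all listed genes as background, which hold more unexpressed genes, lists that had lain outside came inside 2.5 to 97.5 (mature B percentile 77.7, dendritic percentile 41.4, erythroid percentile 62.5, thymic epithelium percentile 50.9, stroma and endothelium percentile 64.6) and others went above (ETS factors percentile 98.6, cytokine JAK-STAT percentile 99.91, leukaemia genes percentile 99.95, apoptosis percentile 99.63).

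List differences lost, or with unchanged sign gained, a place outside percentiles 2.5 to 97.5 as follows, and the cause was not tested. Numbers after a list's name are the leukaemias compared, and values in brackets are median member differences on the log2 scale, or mean ones with list means. With a pseudocount of 0.1, myeloid 1 minus 2 (0.41), stroma and endothelium 1 minus 3 (0.89), leukaemia genes 1 minus 3 (0.25), immediate early and stress 1 minus 2 (0.43) and sex-linked 1 minus 2 (-0.39) came inside, and NK cell 2 minus 3 (-0.42) and erythroid 1 minus 3 (1.10) went outside. With a pseudocount of 0.01, myeloid 1 minus 2 (0.42), dendritic 2 minus 3 (-0.72), stroma and endothelium 1 minus 3 (0.90), stroma and endothelium 2 minus 3 (0.87), leukaemia genes 1 minus 3 (0.25), immediate early and stress 1 minus 2 (0.44), sex-linked 1 minus 2 (-0.57) and sex-linked 2 minus 3 (0.59) came inside, and NK cell 2 minus 3 (-0.45) and erythroid 1 minus 3 (2.34) went outside. With list means, targeted 2 minus 3 (0.35), pan-B 1 minus 3 (0.080), plasma cell 2 minus 3 (0.20), NK cell 1 minus 3 (0.55), myeloid 1 minus 2 (0.19), dendritic 1 minus 2 (0.32), dendritic 2 minus 3 (-0.14), stroma and endothelium 1 minus 3 (0.53), stroma and endothelium 2 minus 3 (0.43), BCR signalling 2 minus 3 (0.21), cytokine JAK-STAT 1 minus 3 (0.26), leukaemia genes 1 minus 3 (0.16) and immediate early and stress 1 minus 2 (0.22) came inside, and erythroid 1 minus 3 (1.04) and cytokine JAK-STAT 2 minus 3 (0.26) went outside. With genes above 0 in both only, dendritic 1 minus 2 (0.18) came inside, and NK cell 2 minus 3 (-0.23) went outside. With FPKM rescaled to the same sum, NK cell 2 minus 3 (-0.21) went outside. With median-of-ratios factors, sex-linked 1 minus 2 (-0.38) came inside, and NK cell 2 minus 3 (-0.20) went outside. With interval midpoints, dendritic 1 minus 2 (0.20) and sex-linked 1 minus 2 (-0.35) came inside.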

Other observations

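The tests of the 3 patterns weighed below were chosen after the results were seen. The design holds 1 group, so explanations were weighed only by values within these libraries. The genes of this and the next paragraph were chosen after their values were seen. Foxf1, a forkhead transcription factor gene on chromosome 8, 121084386 to 121088154, stood at 0.404, 3.71 and 22.4 FPKM, and the neighbouring long non-coding RNA gene Fendrr, on chromosome 8, 121054882 to 121083110, at 0.101, 0.693 and 5.14. Y-linked genes did not vary together: Eif2s3y was at 3.50, 45.00 and 4.26 FPKM, Kdm5d at 0.476, 4.73 and 5.40, Uty at 4.59, 4.33 and 0.357 and Ddx3y at 11.3, 14.9 and 10.3. Crip1, the gene with the next highest mean FPKM after Eef1a1, lies 101 kb from the nearest immunoglobulin heavy chain segment of the GENCODE M21 annotation on chromosome 12. Its neighbours were lower, with Crip2 at 22.5, 16.8 and 3.95 FPKM, Mta1 at 52.8, 49.2 and 56.2 and Tmem121 at 24.7, 17.8 and 13.8.

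Chromosome-wide levels differed little. Over 20 chromosomes with at least 50 genes at FPKM of at least 3 in all 3 leukaemias, the median log2 difference of a chromosome departed from that of all genes by at most 0.11. That value belonged to chromosome 18, with 194 genes, between leukaemias 1 and 3. The interferon-induced Ifi27l2a was at 2739.9, 1062 and 821 FPKM, and the overlapping Ifi27 was listed at 0, 167 and 116.

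Genes listed at 0 in some leukaemias and well expressed in others form the first pattern. Of 70 such genes with status OK and FPKM of at least 5 elsewhere, 90% overlapped the locus of another listed gene (exact 95% interval 80.5 to 95.9%). The share was 21.5% (20.6 to 22.4%) of 8018 genes of status OK above 0 in all 3 and with FPKM of at least 5 in any. Ddit3 overlaps Mars, and Cog4 overlaps Sf3b3. A candidate explanation, as a hypothesis, is that fragments of overlapping gene models were given to the neighbour by the authors' assignment. Whether single genes such as Ddit3 also differ in the cells stays open, and reads would be needed to tell.

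For T cell genes higher in leukaemia 1, residual T cells may add transcripts. Of 14 members with FPKM of at least 1 in leukaemia 1, 10 were higher there by at least 1 than in both others. Bcl11b, Gata3, Zap70 and Cd28 were the exceptions. This lay between the bounds set for and against the explanation, after the values were seen. The count restates the pattern, and T cell genes in the leukaemic cells would give it too, so it cannot decide for residual T cells. None of these genes is in another list, 9 of the 15 fixed were expressed in all 3 leukaemias, and Cd3g, at 41.8, 9.83 and 8.97 FPKM, was the most abundant that differed. The values argue against scaling of the library, which would raise all genes by 1 factor: the median log2 ratio over the mean of the other leukaemias was 1.69 for these T cell genes and 0.00597 for all 10412 genes with FPKM of at least 1 in any leukaemia (quartiles -0.28 to 0.29). A lower share of leukaemic cells with all other cell types raised alike was set against the myeloid genes. Their median log2 ratio was 0.59 (quartiles 0.41 to 0.87), below the T cell quartiles of 1.08 to 1.92, which argues against such an even rise. NK cell genes were not part of this test, and their median member differences were 1.45 and 0.96 against leukaemias 2 and 3. A lower share with cell types raised unevenly stays open, and residual T cells would be a case of it. Residual T cells and T cell genes in the leukaemic cells themselves cannot be told apart here, since bulk RNA does not part cells.

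Spi1 transcripts in all 3 leukaemias are the third pattern. Myeloid cells express Spi1 and could be its whole source. The log2 difference of Spi1 between leukaemias 2 and 3 was -0.0779, at most 0.21 with the relative widths of its deposited intervals. All 9 myeloid genes with FPKM of at least 1 in all 3 (Csf1r, Lyz2, Adgre1, Fcgr3, S100a8, S100a9, Cd68, C1qa and C1qb) differed by 0.38 to 2.65. That argues against cells marked by these genes as the whole source of Spi1. The lower myeloid members, near the floor, differed by 0.01 (Csf3r), 0.09 (Cd14), 0.26 (Itgam), 1.29 (Mpo) and 1.38 (Elane). Dendritic genes were not part of this test, and their median member difference in this pair was -0.11. Between leukaemias 1 and 2, Spi1 differed by 0.71 and the 9 myeloid genes by -0.61 to 0.68. Transcripts of remaining exons, of undeleted alleles, of myeloid cells in part and of dendritic cells stay open, since gene-level FPKM does not part them.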
